A study of Mus musculus with 20 samples.

How the data were processed

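RNA from a clone of V6.5 mouse embryonic stem (ES) cells carrying a Zscan4-ERT2 transgene was hybridised to 20 Agilent 2-colour oligonucleotide arrays, 2 for each of 10 groups defined by day and tamoxifen schedule. Per the labels, the sample was labelled with Cy3 (green channel) and a common reference with Cy5 (red channel) on every array. The reference was an equal pool of RNA from 11 mouse cell lines, to which ES cell RNA had been added. No array had the dyes exchanged, so a dye effect on a probe cancels only in differences between groups.

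The scanner files hold linear intensity values for both channels, written by Agilent Feature Extraction 9.5.1.1 per the file headers: the mean signal and local background of each spot, the processed signal after Agilent's own background subtraction and dye normalization, and flags for signal over background, saturation and non-uniformity. Each file held 43451 spots, of which 42034 carried 60-base probes for 42006 distinct probe identifiers, and 7 probes were spotted 5 times. The deposited series matrix holds 25030 values per array on a log10 scale, matched to spots by feature number. Its columns correlated with log10 of the processed sample signal at r of 0.9935 to 0.9973 across spots, their medians lay between 2.305 and 2.336, and how the authors centred and normalized them is not given in the sources used here. Those values served as an alternative.

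The files give the probe identifier in place of a gene name for every probe, and the supplied list of mouse genes matched 0 of them. Probes were therefore tested one by one, without choosing a probe per gene. The 22 gene lists fixed in advance and the choices between probes of a gene could not be applied, and probes are named here by identifier and sequence only.

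Mean signals were background corrected with normexp (offset 50) and normalized by loess within each array with limma 3.58.1 in R 4.3.3. Control spots entered normexp, had weight 0 in loess and were then dropped. Spots marked as non-uniform outliers were set to missing (91 values among the tested probes), and spots of one probe were averaged. On the first untreated day 1 array, 12 local backgrounds exceeded 10 times the median background of their channel, the highest being 65209 in the sample channel. They disturbed the normexp fit of the whole array and lowered its correlation with its replicate to 0.8604. Backgrounds above that limit were replaced by the array's median, after which the correlation was 0.9845. This replacement was chosen after seeing the data, and counts without it are given with the alternatives.

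Log2 ratios of sample over reference were the values tested. A probe was kept if its sample channel was well above background on both arrays of at least 1 group, which left 29414 probes. One group-means model with 10 residual degrees of freedom was fitted with lmFit and eBayes (prior degrees of freedom 6.93) to all 20 arrays, and 13 contrasts were taken from it. A probe was called changed at a Benjamini-Hochberg adjusted p under 0.05, without a fold limit unless one is stated. Folds are on the scale of background-corrected signals with the offset added, which understates changes of dim probes. Arrays of 2 per group limit the precision. The labels do not say whether the 2 arrays of a group came from separate cultures, so p-values measure the spread between these arrays, which may be technical.

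The 20 arrays lay on 5 slides of 4 arrays. Slide 1 held day 0 and untreated day 1, slide 2 held day 1 with tamoxifen and untreated day 2, slide 3 both tamoxifen groups of day 2, slide 4 those of day 3 and slide 5 those of day 4. Each group lay on 1 slide, so a slide term could not be fitted beside the groups. Differences between continued and withdrawn tamoxifen lie within a slide and are within-slide values as given. Differences between tamoxifen and no tamoxifen span 2 slides of one scanning session, and those between day 4 and day 0 span scanning sessions.

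The contrasts, the tests and most alternatives were fixed before the data were examined. The rule for named probes asked for the largest called changes whose arrays did not overlap, among probes with a gene symbol. Without symbols it was applied to the day 1 comparison alone, with 2 probes in each direction. Another grouping of probes was set after seeing that no names were given: probes with a sample over reference log2 ratio above 1 on both day 0 arrays (1839, called ES-high here) and below -1 on both (3537, called pool-high). For comparisons that contain day 0, the same classes were set on the untreated day 2 arrays instead (1826 and 3494 probes). Their shifts were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over 16 tests. On data simulated from these arrays for continued against withdrawn tamoxifen on day 2, with 200 changed probes among 29414, the fit called 60% of 1.25-fold changes and 100% of 1.5-fold changes, and 11 unchanged probes.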

Results

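Zscan4 genes encode zinc finger and SCAN domain proteins expressed in early mouse embryos and, at any one time, in a small share of cultured ES cells. In the ES-ZERT cells studied here, numbered 18 in the labels, Zscan4 is fused to ERT2, a modified oestrogen receptor domain that holds its partner inactive until tamoxifen is added. Cells were plated as a monolayer and sampled on day 0 and on days 1, 2, 3 and 4. Untreated cells were used for days 1 and 2. Cells in 200 nM tamoxifen throughout were sampled on each of the 4 days, and cells given tamoxifen on day 1 only, then plain medium, on days 2, 3 and 4. All 10 groups had 2 arrays. Between 26199 and 30069 of the 42006 probes were well above background in the sample channel of an array. Replicate arrays correlated at 0.9845 to 0.9954 across the 29414 probes tested, and arrays of different groups at 0.7544 to 0.9958.

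The first and second principal components held 62.2% and 16.1% of the variance of the probes. Most days and schedules also lay on different slides, so neither component can be credited to time in culture or tamoxifen alone. On the second component the day 0 and untreated arrays lay between -25.9 and -9.71. All tamoxifen-treated arrays of days 1 to 3, withdrawn or not, lay between 12.5 and 23.9. On day 4 the withdrawn arrays were at -20.7 and -23 and the continued arrays at -1.13 and -5.89. On the first component, however, these withdrawn arrays were at -52.1 and -54 and the continued ones at -56.5 and -60.1, far from the day 0 and untreated arrays, which lay between 16.8 and 54.9.

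**Figure D1:**
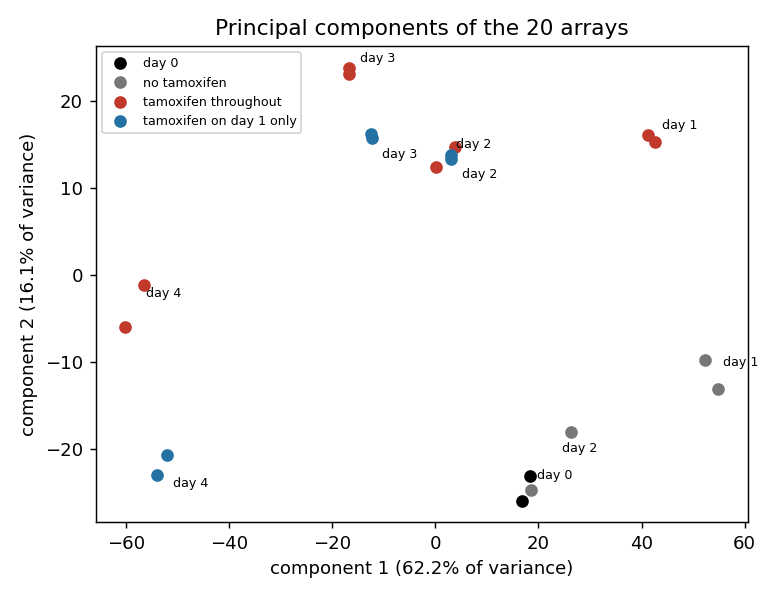
Each point is 1 array placed by its scores on the first and second principal components of log2 sample over reference (29325 probes with no missing value), coloured by tamoxifen schedule and marked with its day. The 2 day 2 groups given tamoxifen overlap, and on day 4 the withdrawn arrays (-20.7 and -23 on component 2) lie below the continued ones (-1.13 and -5.89).

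To find the first response to tamoxifen in these cells, cells with tamoxifen were compared with untreated cells of day 1. After 1 day, 2737 probes were higher and 2762 lower than in untreated cells (limma, adjusted p under 0.05), 18.7% of those tested. Most changes were small: 57 of the higher and 81 of the lower probes reached 2-fold. The largest rise among probes whose arrays did not overlap was that of probe Z00037943-1, 3.5-fold (log2 change 1.81, SE 0.062, limma adjusted p = 7e-12). Probe Z00024009-1 rose 3.19-fold (log2 1.67, SE 0.077, adjusted p = 1.5e-10). The largest fall was that of Z00010943-1, by 7.58-fold (log2 -2.92, SE 0.14, adjusted p = 1.7e-10), followed by Z00046636-1, 4.09-fold (log2 -2.03, SE 0.059, adjusted p = 1.1e-12; log2 -0.907 with the local backgrounds as given). In untreated cells the 4 probes moved the other way from day 0 to day 1 (log2 -0.88, -0.62, 1.5 and 0.68 in the order named), so part of each difference came from the untreated cells. With tamoxifen on day 1 they were at 0.16, 2.02, -0.58 and 1.52 (log2 sample over reference), against -0.77, 0.97, 0.84 and 2.87 on day 0. The files do not pair these identifiers with genes. In the order given, the probe sequences are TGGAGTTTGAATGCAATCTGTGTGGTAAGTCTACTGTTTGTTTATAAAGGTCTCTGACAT, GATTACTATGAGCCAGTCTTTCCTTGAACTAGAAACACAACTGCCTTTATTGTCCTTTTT, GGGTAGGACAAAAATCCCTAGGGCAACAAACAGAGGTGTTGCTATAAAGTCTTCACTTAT and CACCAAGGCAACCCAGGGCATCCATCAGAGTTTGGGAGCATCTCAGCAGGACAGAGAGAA. The number of called probes depended on the untreated arrays: it was 8518 without the first of them, whose replicate difference had the widest spread (SD 0.18 against 0.0909 to 0.125 in other groups), 3372 without the second and 2994 without the second tamoxifen array. With only these 4 arrays in the fit it was 1794.

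**Figure D2:**
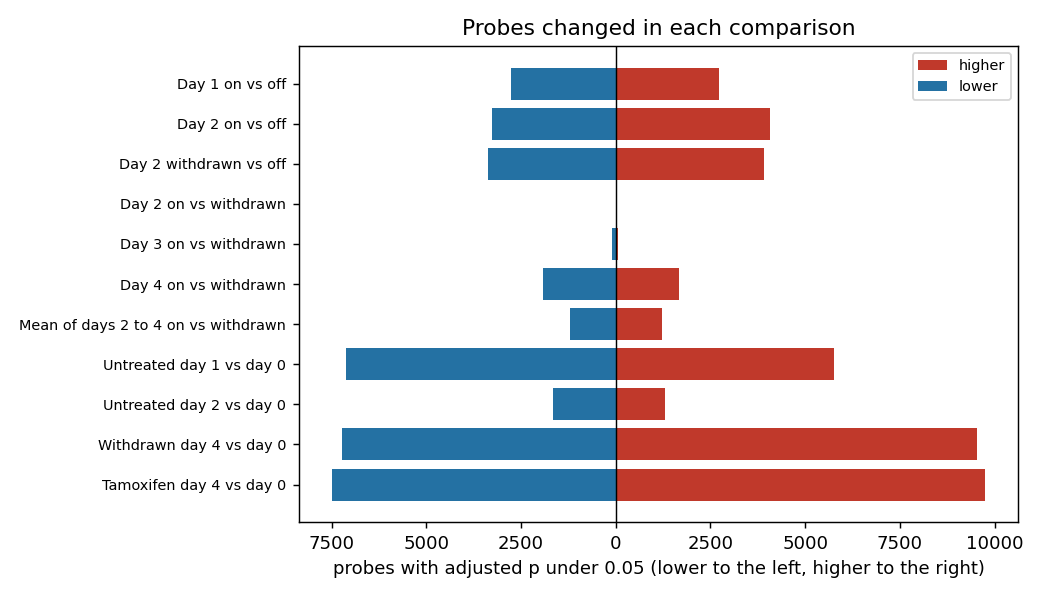
Bars give the number of probes with a limma adjusted p under 0.05 in each comparison of 2 arrays against 2 (6 against 6 for the mean of days 2 to 4), higher in the first-named group to the right and lower to the left. On is tamoxifen throughout, off is no tamoxifen and withdrawn is tamoxifen on day 1 only. Continued and withdrawn cells differed at 0 probes on day 2, 148 on day 3 and 3601 on day 4.

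On day 2, cells kept in tamoxifen differed from untreated cells at more probes, 4071 higher and 3269 lower, with 133 and 180 of them at least 2-fold. Probe Z00037943-1 was 4.01-fold higher (log2 2.00, SE 0.062, limma adjusted p = 4.2e-13) and Z00024009-1 2.18-fold higher. Z00010943-1 was 12.6-fold below untreated cells (log2 -3.65, SE 0.14, adjusted p = 2.6e-12) and Z00046636-1 7.75-fold below (log2 -2.95, SE 0.059, adjusted p = 2.1e-15). The size of these falls depended on the processing: Agilent's processed signals gave log2 -5.09 and -3.67, and the series matrix -3.68 for Z00046636-1. With the local backgrounds as given, which differ on 1 untreated day 1 array only, 3688 probes were called on day 2 and 5410 on day 1. The larger count on day 2 thus did not hold there. It held without background correction (7402 against 5700), with Agilent's processed signals (6312 against 4611) and with median centring (5968 against 4261). It also held in the sample channel alone (6750 against 5022) and in the series matrix (5333 against 4093). The day 1 count rose above the reported day 2 count when the first untreated day 1 array was left out.

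The day 1 and day 2 responses were largely shared. Of the probes called in both comparisons, 1719 were higher on both days and 1845 lower on both, where independent lists of these lengths would share 379 and 307. Only 19 of the 3583 probes called in both comparisons changed in opposite directions. These comparisons have no array in common, and slide 2 enters them with opposite sign. Across probes, which are not independent replicates, the fold changes of the 2 days correlated at r = 0.751. With only the groups compared in each fit, 1635 probes were shared in place of 3564, and with the local backgrounds as given 1692.

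The size of the response was tested for a difference between the 2 days. At 694 probes the day 2 effect of tamoxifen differed from the day 1 effect, and at 478 of them it had the same sign and was larger on day 2. Slide 2 enters the 2 effects with opposite sign, so a deviation of that slide adds up in their difference. Deviations of slides 1 and 3 enter it too. A slide difference is therefore not separated from a change in the response. The fall of Z00046636-1 was deeper on day 2 (log2 difference -0.92, SE 0.083, limma adjusted p = 1.5e-05). The excess of Z00024009-1 over untreated cells was smaller on day 2 by 0.55 (log2 change -0.55, SE 0.11, adjusted p = 0.0099). Its level with tamoxifen went up from 2.02 on day 1 to 2.81 on day 2 (log2 sample over reference), while that in untreated cells went from 0.35 to 1.69. For Z00037943-1 and Z00010943-1 the change from day 1 to day 2 did not pass the test (adjusted p = 0.28 and 0.054). This count was unstable, at 4145 without the first untreated day 1 array, between 332 and 450 without any of 6 others that moved it, and 158 with only these groups in the fit.

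Withdrawal was tested first after 1 day in plain medium, to ask what remained of the response. Cells withdrawn on day 2 still differed from untreated cells at 7277 probes, 3903 higher and 3374 lower. Of the probes changed on both days 1 and 2, 1608 of the 1719 risers and 1759 of the 1845 fallers were called the same way in withdrawn cells. Median log2 changes against untreated cells were 0.41 in continued and 0.40 in withdrawn cells for the risers, and -0.43 in both for the fallers. Z00037943-1 was 3.74-fold higher in withdrawn than in untreated cells and Z00010943-1 11.6-fold lower. Both comparisons use the same untreated arrays, and both set slide 3 against slide 2, so a difference between these slides would enter both alike. Their fold changes correlated at 0.9645 across probes, against 0.4953 in simulated groups without effect, and their covariance was 0.06524 against 0.002945. Calls shared by both numbered 3284 higher and 2809 lower, where independent lists would share 540 and 375. Part of this excess may come from the shared untreated arrays or from the shared pair of slides, which the simulation did not include. The simulated groups held no effect, so their 0 shared calls were near certain in advance. They do not show how many calls shared arrays add between 2 real responses. Under median centring in place of loess, 65.4% of the calls in withdrawn cells were higher, against 53.6%, and with the local backgrounds as given 3559 probes were called.

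Set directly against each other on day 2, continued and withdrawn cells differed at 0 probes by limma. At an unadjusted p under 0.05 there were 819 probes, where 1471 are expected by chance. The central 95% of log2 differences lay between -0.13 and 0.14. In the shared risers the median difference was 0.02 and in the shared fallers -0.01. Quantile-normalized sample signals alone gave 1 probe and the series matrix values 2, and leaving out 1 array gave 2 to 9.

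**Figure D3:**
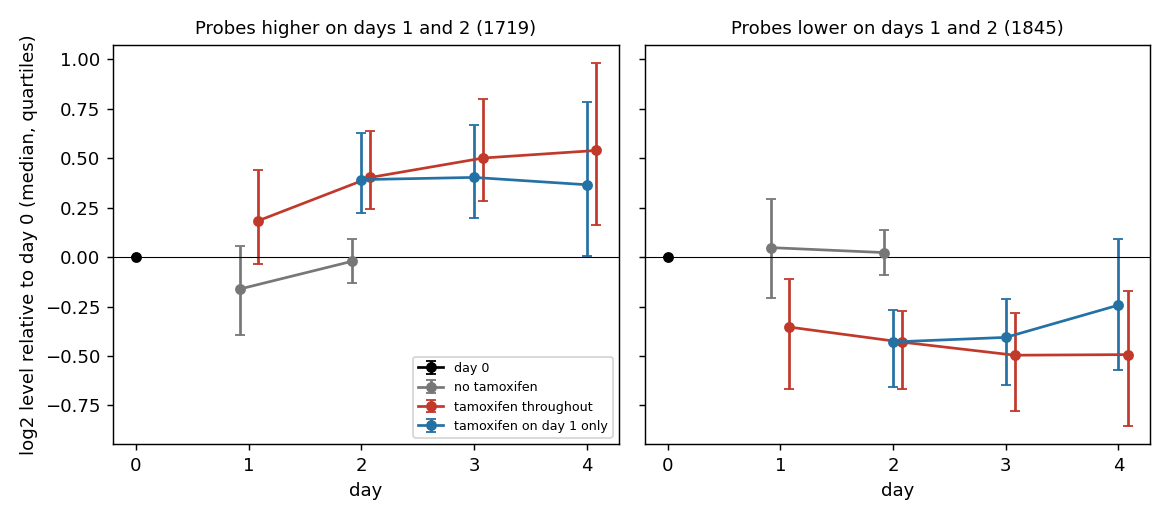
Median log2 level relative to the day 0 mean, with lower and upper quartiles over probes, by day for the 1719 probes higher and the 1845 probes lower with tamoxifen on both days 1 and 2, by tamoxifen schedule (2 arrays averaged per point). Continued and withdrawn cells coincide on day 2 (0.40 and 0.39 for the risers) and separate by day 4 (0.54 and 0.37).

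By day 3, 2 days after withdrawal, small differences had appeared. Continued cells were higher than withdrawn cells at 46 probes and lower at 102, and 145 of these 148 were called in the same direction on day 4. Of the higher probes, 40 were among the shared risers (3 expected), and of the lower, 99 were among the shared fallers (6 expected). Z00010943-1 was 1.98-fold lower in continued cells (log2 -0.98, SE 0.14, limma adjusted p = 0.0036) and Z00037943-1 1.35-fold higher (log2 0.43, SE 0.062, adjusted p = 0.0042), while Z00024009-1 had a log2 difference of 0.35 that did not pass (adjusted p = 0.054). Every one of the 4 day 3 arrays mattered: without 1 of them the count was 33, 59, 11 or 91. Agilent's processed signals gave 36 calls, 19.4% of them higher against 31.1%, median centring 86, 41.9% of them higher, and the local backgrounds as given 7.

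On day 4, after 3 days in plain medium, the difference was wide. Continued cells were higher at 1682 probes and lower at 1919, with 6 and 45 at least 2-fold. The shared response accounted for much of it: 697 of the 1719 risers were higher in continued cells and 13 lower, and 996 of the 1845 fallers were lower and 12 higher, where 98 and 120 in the shared direction would be expected of independent lists. Medians were 0.17 for the risers and -0.24 for the fallers, 42.4% and 55.8% of their day 2 effects against untreated cells. From day 2 to day 4 the median log2 level of the risers relative to day 0 went from 0.39 to 0.37 in withdrawn and from 0.40 to 0.54 in continued cells, and that of the fallers from -0.43 to -0.24 and from -0.43 to -0.49. Z00037943-1 was 1.54-fold higher in continued cells (log2 0.62, SE 0.062, limma adjusted p = 3.2e-06), Z00024009-1 1.32-fold higher (log2 0.40, SE 0.077, adjusted p = 0.0019) and Z00010943-1 1.75-fold lower (log2 -0.81, SE 0.14, adjusted p = 0.00058). Z00046636-1 was not well above background on either continued array of day 4, so no fold is given for that day. A further 405 higher and 437 lower probes on day 4 had been called on neither day 1 nor day 2 against untreated cells. Leaving out any 1 of the 4 arrays gave 1933 to 2351 calls, and the local backgrounds as given 1114.

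By the test of the difference itself, continued minus withdrawn was more positive on day 4 than on day 2 at 397 probes and more negative at 732, and 1108 of these 1129 were called on day 4 with the same sign. It was so for Z00037943-1 (log2 0.52, SE 0.088, adjusted p = 0.0019) and Z00024009-1 (log2 0.47, SE 0.11, adjusted p = 0.019), and missed the threshold for Z00010943-1 (log2 -0.69, SE 0.19, adjusted p = 0.056). Averaged over days 2 to 4, with 6 arrays a side compared within slides, 1226 probes were higher and 1203 lower in continued cells, and 0 of them reached 2-fold. With the local backgrounds as given, the counts were 250 for the change from day 2 to day 4 and 630 for the average. Agilent's processed signals gave 621 for the former, median centring 740, and leaving out an array 679 to 883.

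**Figure D4:**
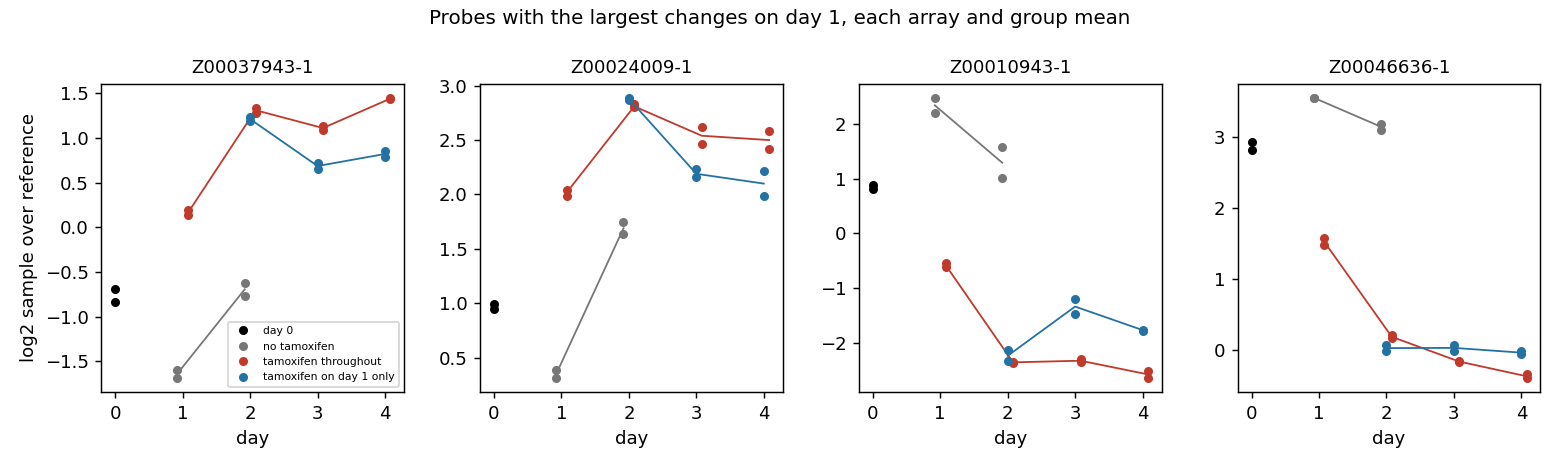
Log2 sample over reference by day for the 4 probes with the largest changes on day 1, each point 1 array and each line the mean of a schedule. On day 4, Z00046636-1 in continued cells (-0.37) was not well above background on either array, so that point is only an upper bound.

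Levels of the 4 probes were followed from day 2 to day 4 in withdrawn and continued cells. Z00037943-1 stood at -0.77 ± 0.095 (log2 sample over reference, SD, n = 2) on day 0. In withdrawn cells it was at 1.21 ± 0.028, 0.69 ± 0.042 and 0.82 ± 0.049 on days 2, 3 and 4, and in continued cells at 1.31 ± 0.034, 1.11 ± 0.026 and 1.44 ± 0.019. Z00024009-1 was at 0.97 ± 0.032 on day 0, at 2.88 ± 0.014, 2.19 ± 0.05 and 2.10 ± 0.16 in withdrawn cells, and fell in continued cells too, from 2.81 ± 0.016 to 2.54 ± 0.11 and 2.50 ± 0.12. Z00010943-1 was at 0.84 ± 0.051 on day 0, at -2.24 ± 0.15, -1.34 ± 0.19 and -1.77 ± 0.022 in withdrawn cells and at -2.36 ± 0.02, -2.33 ± 0.038 and -2.58 ± 0.1 in continued cells. Z00046636-1 was at 2.87 ± 0.08 on day 0 and at 0.03 ± 0.064, 0.03 ± 0.053 and -0.04 ± 0.028 in withdrawn cells, with 0.18 ± 0.032 and -0.16 ± 0.0061 in continued cells on days 2 and 3.

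Probes were not matched to genes here, but the common reference gives a second description of each probe. ES-high probes had a day 0 signal more than 2 times that of the pool of cell lines and ES RNA. Dye effects on a probe do not cancel in this ratio, so the classes may partly reflect them. ES-high probes fell more often than they rose with tamoxifen: 441 fell and 275 rose on day 1, and 556 fell and 320 rose on day 2, out of 1839. Pool-high probes went the other way on day 2, with 958 rising and 351 falling out of 3537, against 11.6% rising and 9.83% falling among the 24038 remaining probes. Median log2 changes on day 2 were -0.06 for ES-high and 0.07 for pool-high probes (camera adjusted p = 8.5e-05 and 0.00036; adjusted p = 0.27 and 0.3 with an estimated correlation; fry adjusted p = 0.0027 and 0.0034). Measured as a median log2 difference from other probes, the day 2 pool-high shift of 0.0618 was 0.0367 without the first untreated array, 0.0953 without the second and 0.1 with Agilent's processed signals, and the ES-high shift of -0.08 was -0.0695 to -0.0912 when 1 array was left out. On day 1 the ES-high shift had a camera adjusted p of 0.0099, or adjusted p = 0.39 with an estimated correlation, and the pool-high shift did not pass (adjusted p = 0.24). The day 0 arrays that set the classes shared slide 1 with the untreated day 1 arrays. A deviation of that slide could therefore by itself make ES-high probes appear to fall on day 1. With the local backgrounds as given, both day 1 shifts turned: the median log2 difference from other probes was 0.27 for ES-high in place of -0.05 and -0.565 for pool-high in place of 0.02. Leaving out 1 array gave day 1 shifts of -0.0288 to -0.0594 for ES-high and -0.00242 to 0.0367 for pool-high. Between continued and withdrawn cells on day 4, 523 pool-high probes were higher and 228 lower, and 146 ES-high probes were higher and 333 lower (camera adjusted p = 4.7e-05 and 0.00014, adjusted p = 0.27 for both with an estimated correlation). The ES-high shift of -0.057 on day 4 was -0.0313 without the second withdrawn array and -0.08 without the first, and the pool-high shift of 0.0627 was 0.059 to 0.0717 without 1 array and 0.0327 in the sample channel alone.

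Untreated cells were followed for changes without tamoxifen. The day 1 comparison with day 0 lies within slide 1, whereas that of day 2 sets slide 2 against slide 1 and may include a slide difference. Untreated day 1 cells differed from day 0 cells at 12878 probes, 5759 higher and 7119 lower, and untreated day 2 cells at 2960, 1306 higher and 1654 lower. The probes higher on day 1 had a median log2 change of 0.32 on that day and 0.08 on day 2, and those lower on day 1 had -0.34 and -0.09. Because the day 1 comparison chose these probes, their day 1 medians are overstated. Z00010943-1 was 2.84-fold above day 0 in untreated cells on day 1 (SE 0.14 on the log2 scale, limma adjusted p = 1.5e-07), and 1.37-fold above it on day 2 (adjusted p = 0.041). The day 2 count was 1248 without the second day 0 array, 1237 without the first untreated day 2 array, 1807 with Agilent's processed signals, 1780 with median centring and 621 with the local backgrounds as given. With only the groups compared in the fit the counts were 8035 and 1832.

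On day 4, withdrawn cells differed from day 0 at 16758 probes, 9525 higher and 7233 lower, and continued cells at 17263, 9760 higher and 7503 lower. The larger number of higher calls depended on the scaling: the sample channel alone gave 7539 higher and 7897 lower, and 8037 and 8397, and the series matrix 5563 and 5556, and 5678 and 5690. The reference channel alone, whose RNA was common to all arrays, gave 693 and 1051 calls in these 2 comparisons. Pool-high probes, set here on untreated day 2 arrays, were higher in withdrawn day 4 cells at 2002 and lower at 376 of 3494, and ES-high probes higher at 461 and lower at 946 of 1826. Their median log2 changes were 0.26 and -0.22 (camera adjusted p = 5.4e-12 and 1.7e-08, adjusted p = 0.16 and 0.19 with an estimated correlation). The pool-high difference from other probes, 0.242, was 0.371 with the series matrix. Of the probes that rose with tamoxifen on day 2, 2533 were also higher in withdrawn day 4 cells than on day 0, where 1318 would be expected of independent lists. No untreated group of day 3 or 4 was used here, and these comparisons span scanning sessions, so the share of time in culture was not separated from that of the earlier tamoxifen.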

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

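The interaction tests, the comparison in the reference channel and the counts without 1 array were planned before the data were examined. The tests of direction, power, loss after withdrawal, array similarity, array position and other splits, and the bounds by which each explanation was read, were chosen only after results were seen.

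Interaction tests compared the effect of tamoxifen between time points. The difference between continued and withdrawn cells changed from day 2 to day 4 at 1129 probes, among them Z00037943-1 (log2 0.52) and Z00024009-1 (log2 0.47). The effect against untreated cells changed from day 1 to day 2 at 694 probes, among them Z00024009-1 (log2 -0.55) and Z00046636-1 (log2 -0.92).

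The first pattern is that the responses of days 1 and 2 shared their direction although each comparison spans 2 slides. A deviation of slide 2 alone is argued against, because slide 2 holds the treated arrays of one comparison and the untreated arrays of the other. Of the probes called in both, 99.5% had the same sign. A drift from slide 1 to slide 3, or separate deviations of slides 1 and 3, could give the same sign in both and is not decided by this. A difference in hybridisation or scanning that touches both channels should also appear in the quantile-normalized reference channel, where the day 2 comparison gave 20 calls in place of 7340. A technical difference confined to the sample RNA, its labelling or its channel would not appear there, nor would one that quantile normalization removes, so the reference channel cannot decide those. Tamoxifen acting without the fusion protein cannot be told apart from the action of Zscan4-ERT2, since 0 of the 10 groups lack the fusion. Activation of the fusion by tamoxifen therefore stays a hypothesis beside it.

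The second pattern is that continued and withdrawn cells were alike on day 2 and apart on day 4. Too little power on day 2 is argued against, since the shared risers differed by a median of 4.1% of their effect against untreated cells. A slow loss of the response after withdrawal goes with the fallers as a set. Their median level in withdrawn cells moved back toward day 0 by 43.4% from day 2 to day 4. That of the risers moved back by 6.65%, which cannot be told apart from a change with time in culture. Time in culture alone does not separate the schedules on day 4, since both had the same days in culture and lay on slide 5. The riser median went from 0.39 to 0.37 in withdrawn and from 0.40 to 0.54 in continued cells, so loss after withdrawal is not shown for the risers as a set. Levels of days 2 and 4 come from different slides. Single probes differed (Z00024009-1 went from 2.88 to 2.10 in withdrawn cells, and the faller Z00046636-1 did not move back). That the day 2 withdrawn arrays hold cells still in tamoxifen cannot be told apart from a late divergence, because their lowest correlation with a continued array, 0.9944, lies within the range of replicates. For the mean of days 2 to 4, 1 of 100 splits drawn within slides, the real one itself, gave 2429 calls or more (highest other 2317), a rank that by itself is weak evidence against chance: the 5 next highest, 1891 to 2317, differed from it only on day 2, where the groups were alike, and splits that mixed the day 4 groups gave 0.

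The third pattern is that untreated day 1 cells lay further from day 0 than untreated day 2 cells. Array position on the slide is argued against: untreated day 1 minus day 0 on slide 1 and tamoxifen day 1 minus untreated day 2 on slide 2, where the positions of the day 1 arrays are reversed, correlated at 0.619 across probes. The second difference also holds the tamoxifen effect, which on day 2 correlated with the first at -0.134. A single poor array is argued against as well, with 13015 calls left without the array whose backgrounds were replaced. A response to plating or fresh medium that fades by day 2 may be at work, and the design names no group that tests it.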

How the results depend on the processing

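The replacement of outlying backgrounds and its alternative were chosen after seeing the data, and the other alternatives before. Arrays of 2 per group limit the precision of every count, and 24629 of the 42006 probes were well above background on all arrays. The 4 named probes kept their direction on days 1 and 2 under every alternative run that measured them, and all calls but 1, Z00046636-1 on day 1 with backgrounds as given. Counts stayed within 1.5 times the reported ones without background correction, with either filter on dim probes and with trend and robust eBayes. Aquantile leaves the log ratios untouched and so tests nothing here. Choosing or averaging probes per gene, and the 2 alternatives for gene lists, were not run because probes were not matched to genes here. Where counts moved, the cause was not tested unless given.

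With the replicate number as a block, the counts were 5530 on day 1, 7326 on day 2, 0, 160 and 3596 for continued against withdrawn cells on days 2, 3 and 4, and 2427 for their mean. Deviations of same-numbered arrays correlated between -0.288 and 0.284 over 45 pairs of groups, with 9 pairs over 0.1. The numbers thus show no pairing that holds across all groups, while a pairing within some groups is not excluded.

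With backgrounds as given, which differ on 1 array only, the median moderated SD of a probe was 0.0884 in place of 0.0703, and counts were 3688 for day 2 on against off, 3559 for day 2 withdrawn against off, 7, 1114 and 630 for continued against withdrawn on day 3, day 4 and on average, 621 for untreated day 2 against day 0, 250 for day 4 against day 2 effects and 1692 for shared calls. The ES-high shift on day 1, a median log2 difference from other probes of -0.05 as reported, reversed to 0.27 there, and the pool-high shift, 0.02 as reported, went to -0.565.

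Agilent's processed signals gave 36 calls on day 3, 1807 for untreated day 2, 621 for day 4 against day 2 effects and 317 for day 2 against day 1 effects, and median centring 86, 1780, 740 and 420. The sample channel alone gave 1 and the series matrix 2 for day 2 on against withdrawn. The matrix, with 18098 probes tested, gave 11119 and 11368 for withdrawn and continued day 4 against day 0.

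With only the groups compared in the fit, which leaves fewer degrees of freedom, counts were 1794 on day 1, 8035 and 1832 for untreated days 1 and 2 against day 0, 158 for day 2 against day 1 effects and 1635 shared. Such fits still gave 6677 for day 2 on against off and 3535 for continued against withdrawn on day 4. Fewer degrees of freedom alone therefore do not account for the drops. Of these lowered counts, all but that of untreated day 2 involve the untreated day 1 arrays, whose replicate difference had the widest spread (SD 0.18). The spread pooled over all 20 arrays may be too small for them. The reference channel alone, whose RNA was common to all arrays, gave 3 and 20 calls for days 1 and 2 on against off, and 693 and 1051 for withdrawn and continued day 4 against day 0, which span scanning sessions.

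A limit of 1.5-fold left 677 and 1183 probes on days 1 and 2 on against off, 543 shared, 1116 for withdrawn against off, 5, 368 and 16 for continued against withdrawn on day 3, day 4 and on average, 1919 and 195 for untreated days 1 and 2, 4406 and 5056 for withdrawn and continued day 4 against day 0, and 315 and 163 for the differences of effects. A limit of 2-fold left 138, 313, 112, 298, 0, 51, 0, 319, 24, 1228, 1624, 45 and 11 in the same order.

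Leaving out 1 array at a time, with the lone array of its group assumed to vary like the others, gave 2994 to 8518 calls on day 1, 5065 to 5833 on day 2, 2428 to 3739 shared, 4976 to 5657 for withdrawn against off, 2 to 9, 11 to 91, 1933 to 2351 and 1711 to 2090 for continued against withdrawn on days 2, 3, 4 and on average, 10757 to 13015 and 1237 to 2212 for untreated days 1 and 2, 14478 to 15035 and 14943 to 15669 for withdrawn and continued day 4 against day 0, 679 to 883 for day 4 against day 2 effects and 332 to 4145 for day 2 against day 1 effects. The counts above the reported ones on day 1, for shared calls and for untreated day 1 came without the first untreated day 1 array, as did 4145 for day 2 against day 1 effects, where 778 without the second untreated day 2 array was also above.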

Other observations

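All values in this part were chosen after seeing the data. Probes linked by shared stretches of 30 bases formed 6 families of at least 5 tested probes, whose members share sequence and are not separate evidence.

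In one family of 18 linked probes, 0 members were called with tamoxifen on day 1, and 16 were lower on day 2 (median log2 change -0.33) and 14 in withdrawn cells of that day (median -0.29). The change between the 2 days passed the test at 5 members. All 18 were lower than on day 0 in both day 4 groups, with medians of -0.78 in withdrawn and -0.68 in continued cells, and 0 differed between the schedules on day 4. A family of 8 probes was lower at 6 members on day 1 (median -0.27), at 4 on day 2 (median -0.21) and at 1 in withdrawn cells of day 2 (median -0.104). Set directly against each other, continued and withdrawn cells of day 2 differed at 0 of these members (median -0.09). All 8 were lower in untreated cells of day 2 than on day 0 (median -0.54). A family of 5 probes was higher with tamoxifen at 3 members on day 1 and at 5 on day 2 (medians 0.22 and 0.41), at 5 in withdrawn cells of day 2 (median 0.45), and at 3 in continued against withdrawn cells on day 4 (median 0.24). The same 5 were lower in untreated cells of day 1 than on day 0 (median -0.53). The remaining families, of 7, 5 and 5 probes, had 0 members called with tamoxifen against untreated cells on day 2, and on day 1 only 1 member of one family of 5 was called.

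The shared risers moved in the opposite direction in untreated cells of day 1, where 845 of the 1719 were below day 0 and 281 above (median log2 change -0.16). These counts share the untreated day 1 arrays with the comparison that defined the set, which pulls them that way. In a comparison without shared arrays, the change from day 0 to untreated day 1 and the tamoxifen effect of day 2 correlated at -0.134 across probes. The tamoxifen effect of day 2 correlated at 0.433 with the change from day 0 to withdrawn day 4 cells.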
